A study of Mus musculus with 16 samples.

How the data were processed

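Whole-skin RNA of 2 genotypes at 3 times of 4-hydroxytamoxifen treatment, 6 groups in all, was measured on 16 arrays, 1 per sample. Per the labels, biotin-labelled cRNA was made from total RNA and hybridised to Affymetrix Mouse Expression Set 430 A arrays. The deposited values are the intensity of each probe set on a linear scale, 22690 probe sets per array, 64 of them controls. The software that summarised probes to probe sets, and any scaling done with it, is not given in the sources used here. No detection calls, scan dates or batches were used. Samples were grouped by the genotype and day in their titles.

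The trimmed mean of an array, with 2% removed at each end, ranged from 359 to 548, a spread above the 10% set as the limit, so every array was scaled to 1 common trimmed mean by a factor between 0.825 and 1.26. Values were then taken as log2(intensity + 32). The added 32 makes changes from low intensities smaller than the ratio of the intensities, so folds of genes near 0 at day 0 are understated. Kept were the 15058 probe sets above the 40th percentile of their array on at least 2 arrays. Gene symbols came from the platform annotation, and looking them up by gene identifier in the RefSeq names of GRCm38.p6 changed 0 of them. In that annotation 20380 probe sets had 1 symbol, 691 had several and 1555 were not listed, and probe sets without exactly 1 symbol were left out. Of the 13882 kept probe sets with 1 symbol, the brightest on average was taken for each gene, which left 9058 genes, 3242 of them with more than 1 kept probe set. The other probe sets of genes past the threshold went the same way in 1675 of 1919 cases for transgenic day 7 against day 0, and in 22 the opposite way past the threshold. For wild-type day 1 against day 0 these counts were 823 of 1103 and 32.

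Group means of all 16 arrays were fitted in limma 3.58.1 under R 4.3.3, with empirical Bayes variances that follow a trend with intensity and 10 residual degrees of freedom. There were 10 comparisons: each day against day 0 in each genotype, transgenic day 7 against day 1, the genotypes at each day, and the difference between genotypes in the change to day 1 and to day 7. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg's method within a comparison, and a gene was past the threshold at an adjusted p under 0.05. Changes are log2 values with the standard error (SE) of the fit, and intensities are scaled values with the SD between arrays. Pools of shared arrays were not compared, and overlaps are given only between comparisons with no array in common, beside the number that independent lists would share. The depth of an array has no count of reads, and the number of arrays limits the precision given here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

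The 34 gene lists, 19 of pathways, structures and processes and 15 of markers of other cell types in skin, were written before the data were examined, as were the comparisons, the tests, the alternatives and the rule for named genes. They held 563 different genes, 25 of them in more than 1 list. Each list was tested with limma's camera at a preset correlation between genes of 0.01, with an estimated correlation beside it, adjusted over the lists. Members past the threshold were counted over all genes and adjusted over the list alone, and where only 1 count is given the other was equal. Camera compares a list with all other genes, so a list can pass with few members past the threshold.

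Genes were named by a fixed rule: in each comparison up to 8 of the largest rises and 8 of the largest falls, from the largest down, among genes past the threshold whose groups do not overlap (with no condition on overlap for the differences between genotypes). Named too were up to 4 members of each list with the smallest p, or 2 bright members where 0 passed, and a set fixed in advance that includes Ctnnb1, Esr1, Axin2, Lgr5, Ptch1, Gli1, Mki67 and Xist. Exceptions, chosen after their values were seen, are Edar and the control genes on array quality. Arntl, Clock, Cry1 and Nfil3 are named for a later test on clock genes. Pdk4 and Errfi1 are named as the largest differences of a later list of glucocorticoid-responsive genes. Lef1 and Shh, of the fixed set, lay below the filter, Tcf7 and Ddx3y are not analysed here, and 1 more gene of the set is not reported here.

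The fit was tested on simulated data built on the spread of these arrays, with 200 of 9058 genes changed in each of 5 runs per comparison. For transgenic day 7 against day 0 it recovered 64.5% of genes changed 1.5-fold, 93.1% of those changed 2-fold and 100% of those changed 4-fold. For the difference between genotypes in the change to day 1 the shares were 30.4%, 84.5% and 99.4%, and for that to day 7 they were 23.9%, 74.9% and 98.2%.

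Alternatives, changed 1 at a time, were quantile normalization, no further scaling, an added value of 8 or 128, no filter or a filter at the 60th percentile on 3 arrays, all probe sets tested singly, probe sets with a plain ending only (the identifiers without a letter before the last part, which fewer related genes share), only the groups compared, no variance trend, array weights, the replicate number as a block, a change of at least 2-fold as well, and each array left out.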

Results

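Gene expression was measured in whole skin of K14ΔNβ-cateninER mice of line D2 and of wild-type C57BL/6 mice on 16 Affymetrix Mouse 430 A arrays. The transgene places an N-terminally truncated, stabilised β-catenin fused to the ligand-binding part of the oestrogen receptor under the keratin 14 promoter, which is active in basal keratinocytes. The fusion protein is switched on by 4-hydroxytamoxifen, and skin was taken after 0, 1 or 7 days of it. The transgenic groups held 2, 3 and 3 arrays at days 0, 1 and 7, and the wild-type groups held 3, 3 and 2. No array came from skin given vehicle alone, so drug, handling and passing time cannot be separated within a genotype. The labels do not say that every array came from a separate animal, so p-values measure the spread between these samples, part of which may be technical. The trimmed mean intensity of an array lay between 359 and 548, and the ratio of 3' to 5' Gapdh signal between 0.884 and 1.26. Replicates correlated across genes at r = 0.974 to 0.988, genes not being independent replicates. Xist, the transcript of the inactive X chromosome, was bright on every array, at 5436 to 8116, and the Y-linked genes Uty and Eif2s3y stayed at or below 28.8. The number of arrays limits the precision of every value.

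The first principal component held 49.9% of the variance and set the 3 transgenic day 7 arrays, at scores of 38.1 to 51.2, apart from the other 13, all below 0. The second component, with 18.1%, set all day 0 arrays of both genotypes, at 14.8 or more, apart from all day 1 arrays, at -2.14 or less.

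**Figure D1:**
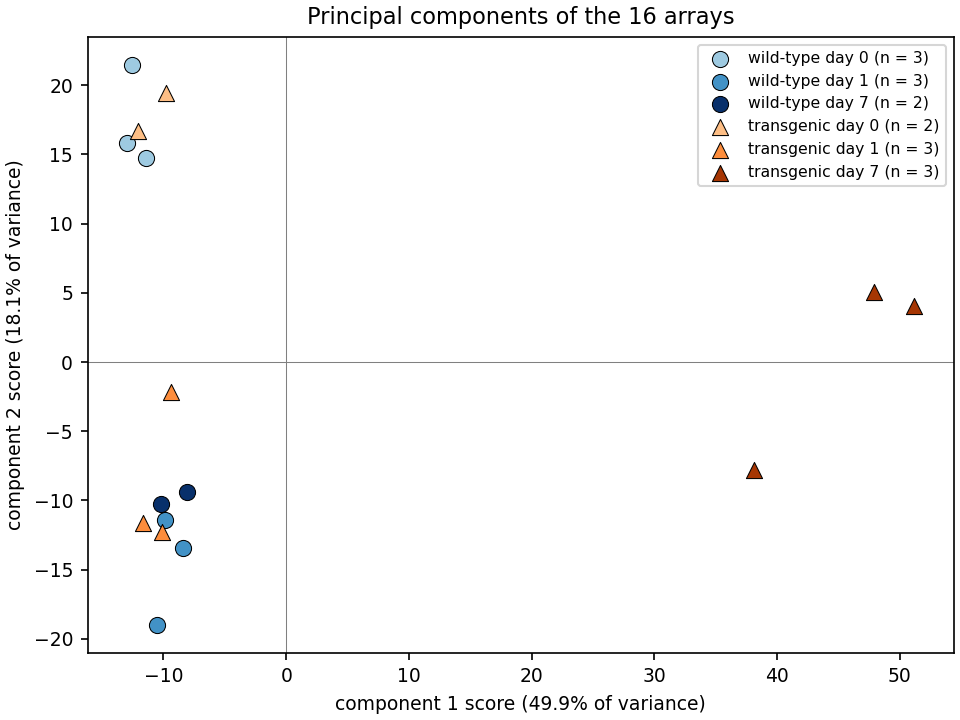
Scores of the 16 arrays on principal component 1 (x axis, 49.9% of the variance, no unit) and component 2 (y axis, 18.1%), from log2 intensities of the 9058 genes tested; each point is 1 array, triangles transgenic and circles wild-type. The 3 transgenic day 7 arrays lie at 38.1 to 51.2 on component 1 and the other 13 below 0.

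The transgenic and wild-type mice were compared before treatment to see how they differed at the start. Esr1, the oestrogen receptor gene whose sequence the fusion carries, was the only gene of 9058 past the threshold. Its intensity was 405 ± 4.61 (SD, n = 2) in transgenic skin and 29.0 ± 18.9 (SD, n = 3) in wild-type skin, a log2 difference of 2.88 ± 0.34 (SE, adjusted p = 0.00335). It was 180 ± 111 against 32.4 ± 14.9 at day 1 and 221 ± 33.5 against 15.8 ± 3.41 at day 7. On single arrays it lay from 80.7 to 408 in the 8 transgenic and from 13.4 to 50.0 in the 8 wild-type samples. Ctnnb1, which encodes β-catenin, differed by 0.01 ± 0.08 at day 0, and the β-catenin target Axin2 by -0.03, the Hedgehog target Gli1 by 0.06 and the proliferation marker Mki67 by -0.11 (adjusted p = 0.994 for each). The unadjusted p was under 0.05 for 413 genes in limma, and 18.9% of genes had groups that did not overlap, against 20% by chance. Among the 34 lists, the dermal fibroblast and matrix markers passed limma's camera test at a median of -0.13 (adjusted p = 0.0143, but adjusted p = 0.989 with an estimated correlation), with 0 of 19 genes past the threshold. That call was lost without transgenic day 0 replicate 2 (-0.11, adjusted p = 0.334) or wild-type day 0 replicate 3 (-0.05, adjusted p = 0.527), and the median was 0.03 without further scaling. With either transgenic day 0 array left out, limma called 0 genes, and Esr1 stood at 2.87 without replicate 1 (adjusted p = 0.14) and at 2.89 without replicate 2 (adjusted p = 0.129).

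After 1 day of drug, skin of both genotypes gained transcripts of a kallikrein, of macrophages and of dividing cells. In transgenic skin 598 genes rose and 376 fell, and in wild-type skin 912 rose and 1111 fell. Klk1, which encodes tissue kallikrein, rose most in both, from an intensity of 1.01 to 2209 ± 866 (SD, n = 3) in transgenic skin and from 15.3 to 1656 ± 98.2 in wild-type skin. On the log2 scale this was 6.01 ± 0.29 (adjusted p = 9.98e-09) and 5.25 ± 0.26 (adjusted p = 1.42e-08). In transgenic skin Lrg1 (2.79) and Hp (2.68), which encode acute-phase proteins, came next, followed by the lymphatic vessel and macrophage receptor Lyve1 (2.61), Chil3 (2.61), the placental growth factor Pgf (2.45) and the monocyte chemokine Ccl7 (2.21). In wild-type skin the next were Lyve1 (2.66), Pgf (2.60) and the monocyte chemokines Ccl2 (2.41), Ccl12 (2.40) and Ccl7 (2.37). C1qtnf3 fell in both, by 1.66 and by 1.36, as did Fndc1 in transgenic skin (-1.42) and the transcription factor Maff (-1.87), Lmod2 (-1.77) and the cytokine receptor Tnfrsf12a (-1.37) in wild-type skin. The other probe set of Tnfrsf12a fell less in wild-type skin, from 163 to 144. Of the genes that rose in transgenic skin, 372 also rose in wild-type skin, against 60.2 for independent lists, and of those that fell 172 also fell, against 46.1.

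Of 18 macrophage and monocyte markers, 16 rose in transgenic skin at day 1 and 17 in wild-type skin, with 17 and 18 adjusted over the list alone. The medians were 1.13 and 1.27 (camera adjusted p = 4.16e-15 and 3.87e-15, but adjusted p = 0.245 and 0.273 with an estimated correlation). The scavenger receptor Msr1 (1.90), Aif1 (1.49) and the mannose receptor Mrc1 (1.19) rose in transgenic skin, and Cd68 (1.77) and Aif1 (1.31) in wild-type skin. The mean of the list was 10.41 on transgenic day 1 replicate 3, against 10.94 and 10.93 on the other arrays of that group, and its ratio of 3' to 5' signal was 1.16 for Gapdh, against 0.916 and 0.958, and 1.87 for actin, against 1.36 and 1.46. Cell cycle genes also rose, 20 of 31 in transgenic and 18 of 31 in wild-type skin, with 27 and 25 adjusted over the list alone. Their medians were 0.62 (adjusted p = 1.03e-17, but adjusted p = 0.188 with an estimated correlation) and 0.52 (adjusted p = 3.61e-12, but adjusted p = 0.273 with an estimated correlation). The mitotic inhibitor-of-apoptosis gene Birc5 rose by 1.19 and by 0.91 in them, and the spindle checkpoint gene Mad2l1 by 1.18 in wild-type skin. Dermal fibroblast and matrix markers rose by a median of 0.34 in transgenic skin (7 of 19 genes, 11 adjusted over the list alone) and of 0.24 in wild-type skin (6 of 19, as many over the list alone). Their camera adjusted p-values were 4.28e-06 and 0.00113, and adjusted p = 0.418 and 0.6 with an estimated correlation. Pdgfra, a receptor of fibroblasts, rose by 1.13 and by 1.11. Vcan, which encodes the matrix proteoglycan versican, rose by 1.34 and 1.13, and the haem oxygenase gene Hmox1 by 1.12 and 1.35.

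Basal epidermis genes fell in wild-type skin at day 1 in 9 of 11 cases and 1 rose (median -0.45, camera adjusted p = 0.000351, but adjusted p = 0.273 with an estimated correlation). Of 20 genes of differentiated epidermis 8 fell, 9 adjusted over the list alone (adjusted p = 8.12e-05, but adjusted p = 0.273 with an estimated correlation), among them the cornified envelope genes Ivl (-1.09) and Cdsn (-0.74). The same list fell in transgenic skin with 3 genes, 6 adjusted over the list alone, at a median of -0.25 (adjusted p = 0.00353, but adjusted p = 0.435 with an estimated correlation). Cholesterol synthesis genes fell in wild-type skin in 8 of 15 cases (adjusted p = 0.000329, but adjusted p = 0.273 with an estimated correlation), such as Msmo1 (-1.08) and Dhcr7 (-0.82). Krt16, a keratin of wounded epidermis, fell by 0.85, and Sox9, a transcription factor of hair follicle stem cells, by 0.91 in wild-type skin. In transgenic skin Sox9 went from 462 to 270, Dhcr7 from 1340 to 1090 and Msmo1 from 2400 to 2270, and Krt16 from 282 to 287. Camera called 12 lists in each genotype, 9 of them lower in transgenic and 8 in wild-type skin, and not all are named here. For 0 of 34 lists did the change to day 1 differ between genotypes, so these falls are not shown to be particular to wild-type skin. No call was made for Ctnnb1 (-0.05), Axin2 (-0.04), Gli1 (0.30) or the Hedgehog receptor Ptch1 (-0.17) in transgenic skin at day 1. The Wnt and β-catenin target list did not pass there either, with 1 of 17 genes higher and 1 lower at a median of -0.14 (camera adjusted p = 0.292).

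The groups of transgenic day 1 and day 0 did not overlap for 41.7% of genes, against 20% by chance, and those of wild-type day 1 and day 0 for 41%, against 10%. The count of 974 genes in transgenic skin fell to 233 without transgenic day 0 replicate 2, to 594 without replicate 1 of that group, and to 633 and 637 without transgenic day 1 replicate 1 or 2. The count of 2023 in wild-type skin fell to 1225 without wild-type day 0 replicate 2 and to 1178 without wild-type day 1 replicate 1. Without further scaling of the arrays 465 genes passed in wild-type skin, 82.2% of them higher, against 45.1% with scaling.

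The difference between the genotypes in the change from day 0 to day 1 was tested directly, and 10 genes were higher and 16 lower by it. Tnfrsf12a differed by 1.81 ± 0.34 (SE, adjusted p = 0.0375), with intensities from 293 to 411 in transgenic and from 217 to 63.1 in wild-type skin, and Cdr2l by 1.65 ± 0.27 (adjusted p = 0.0289), from 37.3 to 243 and from 120 to 162. The other probe set of Tnfrsf12a, not used for the gene, changed less, from 225 to 262 in transgenic and from 163 to 144 in wild-type skin. The difference of 6820431F20Rik was -1.67 ± 0.31 (adjusted p = 0.0374), from 439 to 226 in transgenic and from 246 to 457 in wild-type skin. That of the autophagy gene Wdfy3 was -1.60 ± 0.25 (adjusted p = 0.0289), from 305 to 164 and from 163 to 310, and the transgenic day 0 levels rest on 2 arrays. Tnfrsf12a and 6820431F20Rik missed the threshold without the filter on dim probe sets (adjusted p = 0.0553 and 0.0512) or without a variance trend (0.0517 each), 6820431F20Rik with only the groups compared (0.0804), Tnfrsf12a with a larger added value (0.069) and Cdr2l without further scaling (0.0607). For Ctnnb1, Axin2, Gli1 and Ptch1 the difference was 0.14, 0.29, 0.19 and -0.04, and none passed. Of the 34 lists 0 passed in limma's camera with either correlation, 4 having an unadjusted p under 0.05, but 2 passed without transgenic day 0 replicate 2 or wild-type day 1 replicate 2, and 1 without transgenic day 0 replicate 1, transgenic day 1 replicate 3, transgenic day 7 replicate 3, wild-type day 0 replicate 1 or wild-type day 1 replicate 1. This result depended on single arrays, with 0 genes called without transgenic day 0 replicate 2, transgenic day 1 replicate 1 or wild-type day 0 replicate 2, and 1386 genes at an unadjusted p under 0.05 with all arrays. The counts were 10 without transgenic day 0 replicate 1, 12 and 13 without transgenic day 1 replicate 2 or 3, 8 without transgenic day 7 replicate 1, 9 and 7 without wild-type day 0 replicate 1 or 3, and 3, 15 and 4 without wild-type day 1 replicate 1, 2 or 3. The share of higher genes was 38.5%, 50% after quantile normalization and 14.3% of 7 genes without further scaling.

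Set side by side at day 1, transgenic skin had higher levels of 64 genes and lower levels of 54 than wild-type skin. Tnfrsf12a was higher by 2.22 ± 0.23 (SE, adjusted p = 0.000408), Krt16 by 1.28 ± 0.20 (adjusted p = 0.00939) and the glucocorticoid-induced gene Tsc22d3 by 1.07 ± 0.14 (adjusted p = 0.00214). The other probe set of Tnfrsf12a differed less, at 262 in transgenic and 144 in wild-type skin, against 411 and 63.1 for the one used. Esr1 was higher by 1.61 (adjusted p = 0.0266), but not past the threshold with only the groups compared (adjusted p = 0.0914), without transgenic day 1 replicate 1 (1.22, adjusted p = 0.0612) or without wild-type day 1 replicate 1 (1.67, adjusted p = 0.0737) or 2 (1.41, adjusted p = 0.0848). Of the 34 lists 0 passed in limma's camera, 8 having an unadjusted p under 0.05, but 8 passed without further scaling and 5 without the filter on dim probe sets. With 1 array left out, 2 and 5 passed without transgenic day 1 replicate 2 or 3, 2 without transgenic day 7 replicate 3, 1 without wild-type day 0 replicate 2 or 3, and 1, 3 and 4 without wild-type day 1 replicate 1, 2 or 3. The groups did not overlap for 24.8% of genes, against 10% by chance. The count of 118 fell to 29 and 22 without transgenic day 1 replicate 1 or 3, to 17, 19 and 75 without wild-type day 1 replicate 1, 2 or 3, to 73 without transgenic day 7 replicate 1 and to 63 without wild-type day 7 replicate 1. Without further scaling 16 genes passed, 75% of them higher, against 54.2% with scaling.

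After 7 days of drug, transgenic skin gained the transcripts of growing hair follicles. Against day 0, 1683 genes rose and 1819 fell, 734 of them at least 2-fold, and the groups did not overlap for 59.6% of genes, against 20% by chance. The largest rise was that of Krt25, a keratin of the inner root sheath that encloses the growing hair, from an intensity of 4.60 to 8655 ± 1026 (SD, n = 3), or 7.89 ± 0.20 on the log2 scale (SE, adjusted p = 2.6e-13). The inner root sheath keratins Krt27 (6.44) and Krt71 (6.02), the hair shaft keratins Krt33a (5.88) and Krt35 (5.44), the keratin-associated proteins Krtap8-1 (5.31) and Krtap4-16 (5.29) and the trichohyalin gene Tchh (5.29) followed. Of 23 hair shaft keratin and keratin-associated protein genes 22 rose, at a median of 3.13 (camera adjusted p = 1e-14, but adjusted p = 0.157 with an estimated correlation). Their mean was 8.51 on transgenic day 7 replicate 3, against 9.71 and 10.22 on the other arrays of that group. Of 11 genes of the inner root sheath and companion layer 9 rose and 1 fell, at a median of 3.86 (adjusted p = 3.25e-09, and 0.0336 with an estimated correlation), among them Padi3 (4.51), which encodes an enzyme that modifies trichohyalin. Keratins and keratin-associated proteins form families of similar sequence, so probe sets of one member may also read another.

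Regulators of the follicle rose with these structural genes. Of 16 placode and matrix regulators 10 rose and 2 fell, at a median of 0.90 (camera adjusted p = 9.85e-05, but adjusted p = 0.0916 with an estimated correlation), with Msx2 up by 2.73, Dlx3 by 2.16, Hoxc13 by 1.90 and Cux1 by 1.44. Of 8 Hedgehog pathway genes 5 rose, 6 adjusted over the list alone (median 1.16, adjusted p = 0.000176, but adjusted p = 0.0738 with an estimated correlation). They included Gli1 (2.80) and Ptch1 (2.55), direct targets of Hedgehog signalling, and Gli2 (1.44). Wnt and β-catenin target genes rose in 8 of 17 cases, at a median of 0.37 (adjusted p = 0.000189, but adjusted p = 0.0692 with an estimated correlation). Among them were Bambi (2.39), Sox4 (1.82), the stem cell receptor gene Lgr5 (1.36) and the cyclin gene Ccnd1 (1.02). Mycn, which is not on that list, rose by 2.72. Axin2 stood at 0.15 (adjusted p = 0.275) and Myc at -0.08 without a call. Ctnnb1 rose by 0.39 ± 0.08 (SE, adjusted p = 0.000896), from 5618 ± 262 to 7367 ± 367, and missed the threshold without further scaling of the arrays (0.24, adjusted p = 0.433). Its 2 other probe sets, not used for the gene, had means of 1090 and 2070, and of 2310 and 3820, in transgenic skin at days 0 and 7, against 986 and 1020, and 2130 and 2150, in wild-type skin. Among Wnt ligands, receptors and antagonists 7 rose and 4 fell, 5 adjusted over the list alone, with no call for the list (adjusted p = 0.427), as Wif1 rose by 1.95 and Wnt11 by 1.25 while Sfrp2 fell by 2.67 and Sfrp4 by 1.27. BMP pathway genes rose in 8 of 16 cases and 1 fell (adjusted p = 0.00279, but adjusted p = 0.213 with an estimated correlation), with Smad6 at 1.43. Of 15 Notch pathway genes 5 rose and 3 fell (adjusted p = 0.564), Jag1 rising by 0.89 and Heyl by 1.14.

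Genes of dividing cells and of pigment cells rose as well. All 31 cell cycle genes rose, at a median of 1.68 (camera adjusted p = 2.86e-23, but adjusted p = 0.0685 with an estimated correlation), such as Ccnb2 (2.31), Mki67 (2.24), Top2a (2.21) and Birc5 (2.12). Of 9 melanocyte markers 6 rose, at a median of 1.73 (adjusted p = 9.93e-05, but adjusted p = 0.0738 with an estimated correlation), with the melanosome gene Pmel up by 3.14 and the pigment enzyme genes Dct by 2.87, Tyr by 2.62 and Tyrp1 by 2.49. Dermal papilla markers rose in 2 of 7 cases and fell in 1 (adjusted p = 0.636), Vcan rising by 1.73 and Sox18 by 1.30.

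Among epidermal lists at day 7, basal epidermis genes fell in 5 of 11 cases, at a median of -0.23 (camera adjusted p = 0.0107, but adjusted p = 0.239 with an estimated correlation). These were anchoring genes such as Col17a1 (-1.18), Dst (-0.97), Itgb4 (-0.85) and Lamb3 (-0.75), while the basal keratin Krt14 stood at -0.08. Restricted to probe sets with a plain ending, the list stood at -0.05 (adjusted p = 0.39). Of 20 genes of differentiated epidermis 12 fell and 3 rose, 12 and 4 adjusted over the list alone (adjusted p = 0.0101, but adjusted p = 0.394 with an estimated correlation). The call was lost without transgenic day 7 replicate 3 (-0.38, adjusted p = 0.0736). The barrier lipoxygenase genes Alox12b (-1.68) and Aloxe3 (-0.83) fell, and the suprabasal keratin Krt10 stood at -0.03. Bulge genes split into 5 higher and 5 lower of 17 (adjusted p = 0.755), with the stem cell marker Cd34 down by 1.12. Wound-type genes split into 3 and 3 of 15 (adjusted p = 0.993), as Slpi rose by 1.68 and Krt17 by 0.89 and Serpinb2 fell by 1.87. Sebaceous and sebum lipid genes split into 4 higher and 5 lower of 15, 6 lower adjusted over the list alone (adjusted p = 0.874), with Fads2 at 1.26, Elovl3 at 1.17 and Acsbg1 at -1.50. Cholesterol synthesis genes split into 2 and 2 of 15, 2 and 1 adjusted over the list alone (adjusted p = 0.755).

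Markers of muscle, fat, vessels and nerve were among the genes that fell in transgenic skin at day 7. The largest falls were those of Cyp2e1 (-3.69 ± 0.24, SE, adjusted p = 1.86e-08), the hepcidin gene Hamp2 (-3.32), the clock output gene Dbp (-3.04), the muscle enzyme gene Carns1 (-2.78) and the fat droplet gene Cidec (-2.70). The other probe set of Hamp2 was dim and showed no fall, at 11.7 at day 0 and 13.1 at day 7. Each of these genes was also lower in wild-type skin at day 7 than at day 0. There Cyp2e1 went from 4650 to 1360, Hamp2 from 1950 to 269, Dbp from 2000 to 394, Carns1 from 692 to 349 and Cidec from 1100 to 425. Skeletal muscle markers fell in 17 of 20 cases, 18 adjusted over the list alone, at a median of -1.05 (camera adjusted p = 1.48e-10, but adjusted p = 0.14 with an estimated correlation), such as Ryr1 (-2.14) and Tcap (-1.88). Adipocyte markers fell in 9 of 11, 10 adjusted over the list alone (median -1.26, adjusted p = 6.85e-05, but adjusted p = 0.23 with an estimated correlation), such as Adipoq (-1.49) and Fabp4 (-1.25). Endothelial markers fell in 9 of 12 (adjusted p = 0.00164, but adjusted p = 0.238 with an estimated correlation), such as Vwf (-1.08) and Pecam1 (-0.90), and missed the call under a stricter filter on dim probe sets (adjusted p = 0.11). Schwann cell and nerve markers fell in 4 of 4 (adjusted p = 0.00571, but adjusted p = 0.157 with an estimated correlation), with the myelin gene Mbp at -2.04, and missed it on probe sets with a plain ending (adjusted p = 0.147). T cell markers fell in 4 of 6 (adjusted p = 0.0138, but adjusted p = 0.188 with an estimated correlation), Cd3e by 0.88, and missed the call without the filter or with a stricter one (adjusted p = 0.305 and 0.236). Of 18 macrophage markers 0 passed in limma, in a comparison with 4213 genes at an unadjusted p under 0.05, and Lyz2 stood at 0.26 and Csf1r at -0.01. Their mean was 10.17 on transgenic day 7 replicate 3, against 9.49 and 9.47 on the other arrays of that group.

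Circadian clock genes fell in 9 of 13 cases in transgenic skin at day 7, at a median of -1.22 (camera adjusted p = 4.61e-06, and 0.0202 with an estimated correlation), with Per2 at -2.35, Hlf at -1.68 and Tef at -1.46. Xenobiotic and oestrogen response genes fell in 8 of 12 and 1 rose, 9 and 1 adjusted over the list alone (adjusted p = 0.00315, but adjusted p = 0.0685 with an estimated correlation), such as the detoxifying enzyme genes Aldh3a1 (-1.80) and Gstm1 (-1.07). Interferon response genes fell in 7 of 15 (adjusted p = 0.00318, but adjusted p = 0.452 with an estimated correlation), with Gbp2 at -1.36 and Ifit3 at -1.08. Immediate early and heat shock genes fell in 11 of 19 and rose in 5, among them Nr4a1 (-1.39) and Dusp1 (-1.21). That list passed (adjusted p = 0.0371, but adjusted p = 0.452 with an estimated correlation) and did not pass without transgenic day 0 replicate 1 (-0.42, adjusted p = 0.0766), without transgenic day 7 replicate 3 (-0.44, adjusted p = 0.0733), without further scaling or with a stricter filter. Dermal fibroblast markers rose in 4 and fell in 3 of 19 (adjusted p = 0.636), with Dpt at -1.20. Of the lists with few measured genes, B cell markers fell in 2 of 3, 3 adjusted over the list alone (adjusted p = 0.214, and 0.0276 without transgenic day 0 replicate 2, at a median of -1.88), mast cell markers rose in 1 and fell in 2 of 5 (adjusted p = 0.564), and neutrophil markers passed in 0 of 5 (adjusted p = 0.755). Antigen-presenting cell markers rose in 1 of 9, 0 adjusted over the list alone (adjusted p = 0.716), red blood cell markers in 1 of 1 (adjusted p = 0.136, and 0.0431 without the filter on dim probe sets), and Xist, the 1 sex-linked gene above the filter on dim probe sets, passed over the list alone but not over all genes (0.28, adjusted p = 0.575 for the list). Over all genes it passed on probe sets with a plain ending (1.12, adjusted p = 0.00455) and without wild-type day 1 replicate 3 (0.28, adjusted p = 0.0387). Without further scaling 1776 genes passed between transgenic day 7 and day 0, 29.3% of them higher, against 48.1% with scaling.

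**Figure D2:**
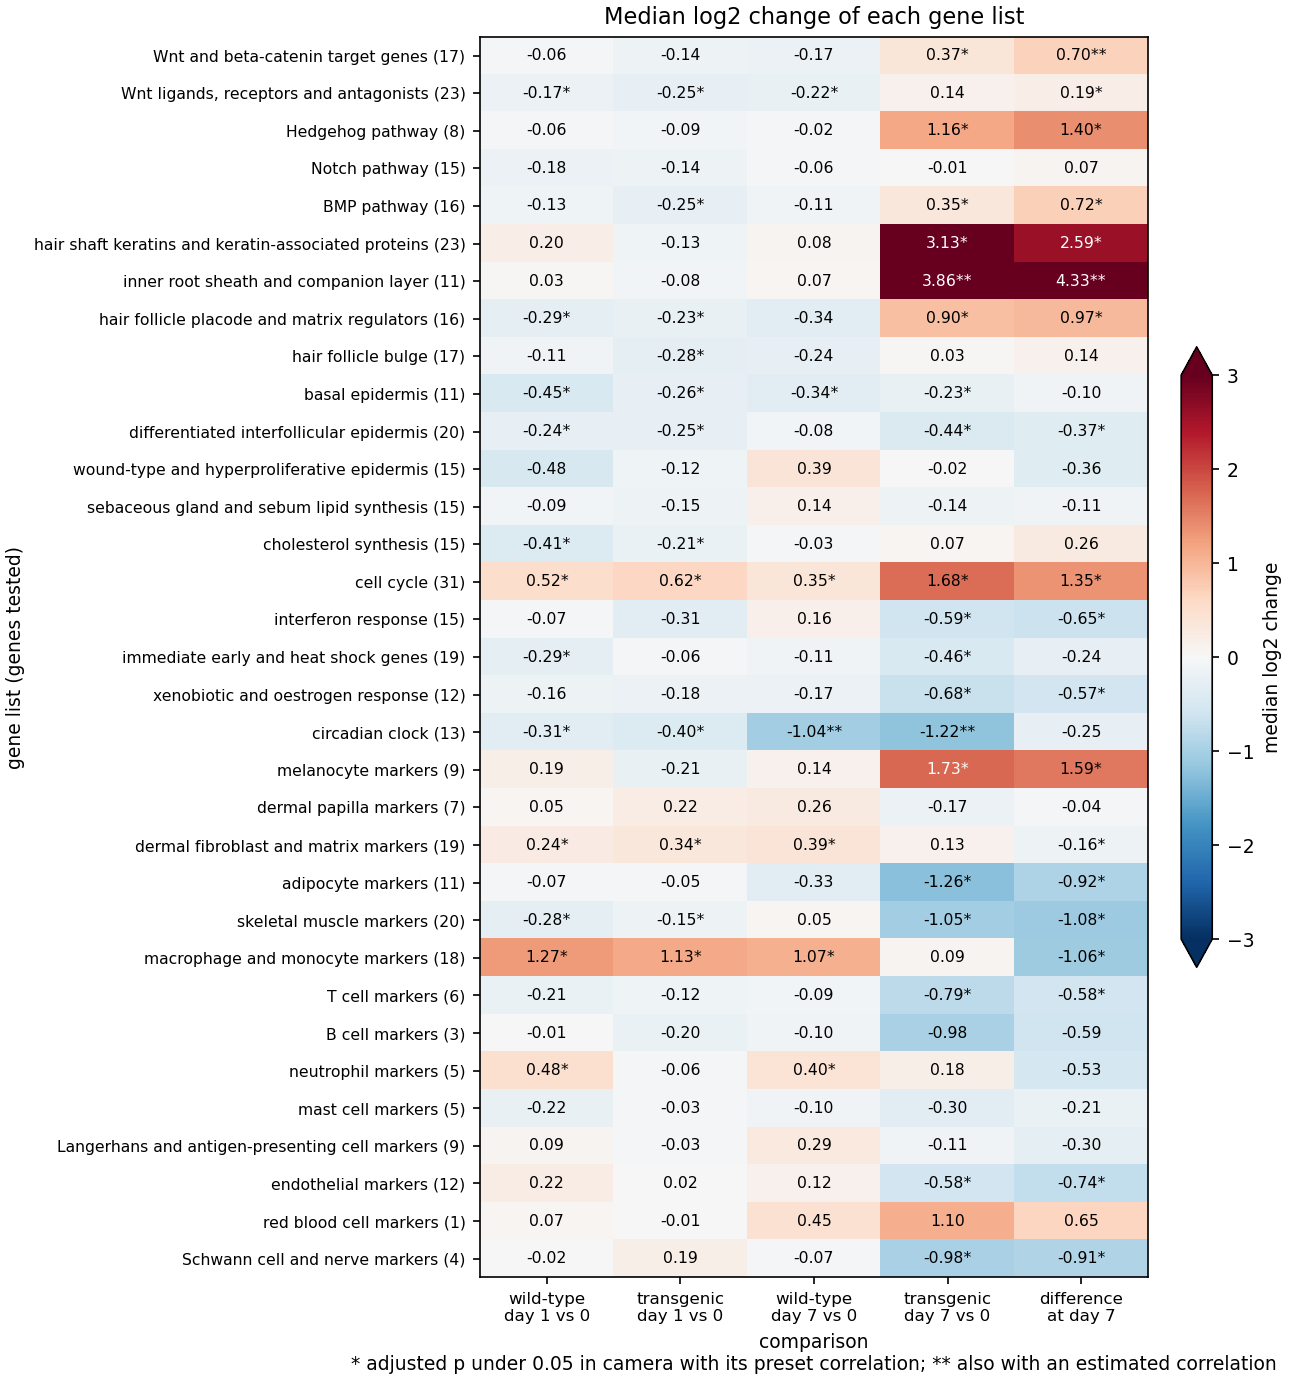
Median log2 change (colour and printed number) of 33 gene lists (y axis, number of genes tested in brackets) in 4 comparisons with day 0 and in the difference between genotypes in the change to day 7 (x axis); 1 star marks an adjusted p under 0.05 in camera with its preset correlation and 2 stars the same with an estimated correlation as well. The hair shaft, inner root sheath, Hedgehog, cell cycle and melanocyte lists rise in the transgenic day 7 column, with hair shaft genes at 3.13 there and at 0.08 in wild-type skin.

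The changes between day 1 and day 7 in transgenic skin, 1950 genes higher and 2059 lower, included rises of follicle genes and falls of macrophage markers. Krt25 rose by 7.93 ± 0.18 (SE, adjusted p = 4.65e-14), Krt27 by 6.81, Gli1 by 2.50, Ptch1 by 2.73, Pmel by 3.58 and the placode regulator Lhx2 by 1.62. All 8 Hedgehog genes rose (camera adjusted p = 3.09e-06, and 0.035 with an estimated correlation). The Chil3 transcript fell most, by 2.88 ± 0.27 (adjusted p = 8.04e-07), followed by the gluconeogenic enzyme gene Pck1 (-2.75). Of 18 macrophage markers 15 fell, 16 adjusted over the list alone (median -1.09, adjusted p = 9.01e-07, but adjusted p = 0.253 with an estimated correlation), such as Ccl7 (-2.29), Msr1 (-1.78) and Cd68 (-1.56). Muscle markers fell in 17 of 20 (adjusted p = 6.63e-09, but adjusted p = 0.137 with an estimated correlation), Ryr1 by 1.81 and Pgam2 by 1.40, and dermal fibroblast markers in 7 of 19 (adjusted p = 0.00666, but adjusted p = 0.461 with an estimated correlation), the lysyl oxidase gene Loxl1 among them (-1.58). The groups did not overlap for 52.4% of genes, against 10% by chance. Of 21 lists past the threshold in this comparison 6 held with an estimated correlation.

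Wild-type skin given the drug for 7 days was examined to see what changes in mice without the fusion gene. Against day 0, 496 genes rose and 540 fell. Klk1 rose further, from 15.3 to 5152 ± 563 (SD, n = 2), or 6.87 ± 0.29 on the log2 scale (SE, adjusted p = 1.33e-09), together with its relatives Klk1b21 (4.15), Klk1b27 (3.87) and Klk1b24 (3.47). These kallikreins are close in sequence, so the values of each may hold signal of the others. Krt2, a keratin of the upper epidermis, rose by 4.31 ± 0.32 (adjusted p = 7.77e-07), from 51.3 to 1651 ± 457, followed by the water channel gene Aqp5 (2.43) and the cornified envelope gene Sprr1b (2.18). Hamp2 had the largest fall (-2.94), but not past the threshold without wild-type day 7 replicate 1 (-2.09). Its other probe set, not used for the gene, was dim, at 13.6 at day 0 and 11.3 at day 7 in wild-type skin. The clock genes Per2 (-2.60 ± 0.16, adjusted p = 1.33e-07), Dbp (-2.27) and Tef (-1.29) and the Wnt antagonist Sfrp2 (-2.44) also fell. Clock genes fell in 8 of 13 cases and rose in 2, 10 and 3 adjusted over the list alone (median -1.04, camera adjusted p = 3.99e-06, and 0.015 with an estimated correlation).

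Of 18 macrophage markers 17 rose in wild-type skin at day 7, at a median of 1.07 (camera adjusted p = 1.99e-15, but adjusted p = 0.301 with an estimated correlation), such as Aif1 (1.26), Mrc1 (1.26), Adgre1 (1.21) and Ctss (0.98). Dermal fibroblast markers rose in 6 of 19, 11 adjusted over the list alone (adjusted p = 5.39e-05, but adjusted p = 0.593 with an estimated correlation). Of 23 hair shaft genes 0 passed in limma (adjusted p = 0.625 for the list), and Krt81 stood at 0.23 and Krt32 at -0.16. Gli1 (0.32), Ptch1 (-0.18) and Axin2 (-0.15) did not pass, nor did any of the 8 Hedgehog genes (adjusted p = 0.956), in a comparison with 2404 genes at an unadjusted p under 0.05. The groups did not overlap for 44% of genes, against 20% by chance. The count of 1036 fell to 328 and 447 without wild-type day 7 replicate 1 or 2 and to 647 without wild-type day 0 replicate 2, and without further scaling 257 genes passed, 64.2% of them higher, against 47.9% with scaling. Transgenic and wild-type skin shared 119 genes higher at day 7, against 92.2 for independent lists, and 298 lower, against 108.4, while 68 rose in transgenic and fell in wild-type skin and 32 the reverse.

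The difference between the genotypes in the change to day 7 was tested directly, which sets aside what changed alike in both. By this test 1096 genes were higher and 1058 lower, 717 of them at least 2-fold. Krt25 differed by 8.04 ± 0.29 (SE, adjusted p = 6.35e-11), Krt27 by 6.15, Krt71 by 5.95 and Krt33a by 5.92. Of 11 inner root sheath genes 8 were higher (median 4.33, camera adjusted p = 1.27e-10, and 0.024 with an estimated correlation), and of 23 hair shaft genes 21, 22 adjusted over the list alone (median 2.59, adjusted p = 1.19e-14, but adjusted p = 0.136 with an estimated correlation). Wnt and β-catenin target genes were higher in 10 of 17 cases, 11 adjusted over the list alone (median 0.70, adjusted p = 1.46e-07, and 0.024 with an estimated correlation), with Bambi at 2.53 and Ccnd1 at 1.69. Axin2 stood at 0.30 (adjusted p = 0.144). Ptch1 (2.73), Gli1 (2.48), Mki67 (1.87) and Pmel (2.80) were also higher. Ctnnb1 was higher by 0.39 (adjusted p = 0.0185), but not past the threshold without further scaling (0.28, adjusted p = 0.666). Nor was it without transgenic day 0 replicate 2 (0.34) or wild-type day 7 replicate 2 (0.31). Its other probe sets, not used for the gene, went from 1090 to 2070 and from 2310 to 3820 in transgenic skin by day 7. In wild-type skin they went from 986 to 1020 and from 2130 to 2150.

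On the lower side of that difference stood Krt2 (-3.25 ± 0.45, SE, adjusted p = 0.000147), Klk1b27 (-2.93), the paraoxonase gene Pon1 (-2.81) and Sprr1b (-2.42). Muscle markers were lower in 16 of 20 cases, 18 adjusted over the list alone (median -1.08, camera adjusted p = 8.46e-12, but adjusted p = 0.102 with an estimated correlation), with Pgam2 at -1.49. Macrophage markers were lower in 11 of 18, 17 adjusted over the list alone (median -1.06, adjusted p = 1.98e-06, but adjusted p = 0.311 with an estimated correlation), with Adgre1 at -1.28 and Aif1 at -1.11. Endothelial markers were lower in 8 of 12, 9 adjusted over the list alone (adjusted p = 1.87e-05, but adjusted p = 0.135 with an estimated correlation), with Tek at -1.47. For clock genes the difference did not pass (median -0.25, adjusted p = 0.124), but passed without the filter on dim probe sets (-0.33, adjusted p = 0.0294). Without further scaling 724 genes passed, 38.8% of them higher, against 50.9% with scaling.

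Transgenic skin at day 7 differed from wild-type skin at day 7 at 3669 genes, 1764 higher and 1905 lower, and the groups did not overlap for 63% of genes, against 20% by chance. Krt25 (7.92 ± 0.20, SE, adjusted p = 2.99e-13) and Krt71 (6.15) were higher, as were Ptch1 (2.75) and Esr1 (2.40). Krt2, at 148 ± 71.1 in transgenic and 1651 ± 457 in wild-type skin, differed by -3.28 ± 0.32 (adjusted p = 1.6e-06), and Klk1, at 1123 ± 81.1 against 5152 ± 563, by -2.16. All 20 muscle markers were lower (median -1.12, camera adjusted p = 1.1e-11, but adjusted p = 0.101 with an estimated correlation), with Pgam2 at -1.58. Macrophage markers were lower in 17 of 18 cases (adjusted p = 1.44e-07, but adjusted p = 0.245 with an estimated correlation), with Cd163 at -1.33 and Mrc1 at -1.19. Of the lists past the threshold in camera, 0 of 12 held with an estimated correlation in each day 1 change, 2 of 19 in transgenic skin from day 0 to day 7, 1 of 7 in wild-type skin over that time, 2 of 19 in the difference between genotypes and 2 of 21 between the genotypes at day 7. The 7 lists of wild-type skin were 11 without wild-type day 7 replicate 1 and 4 without replicate 2. The transgenic line and the wild-type strain can differ in more than the transgene, and the data hold no transgenic mice without drug at day 7.

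**Figure D3:**
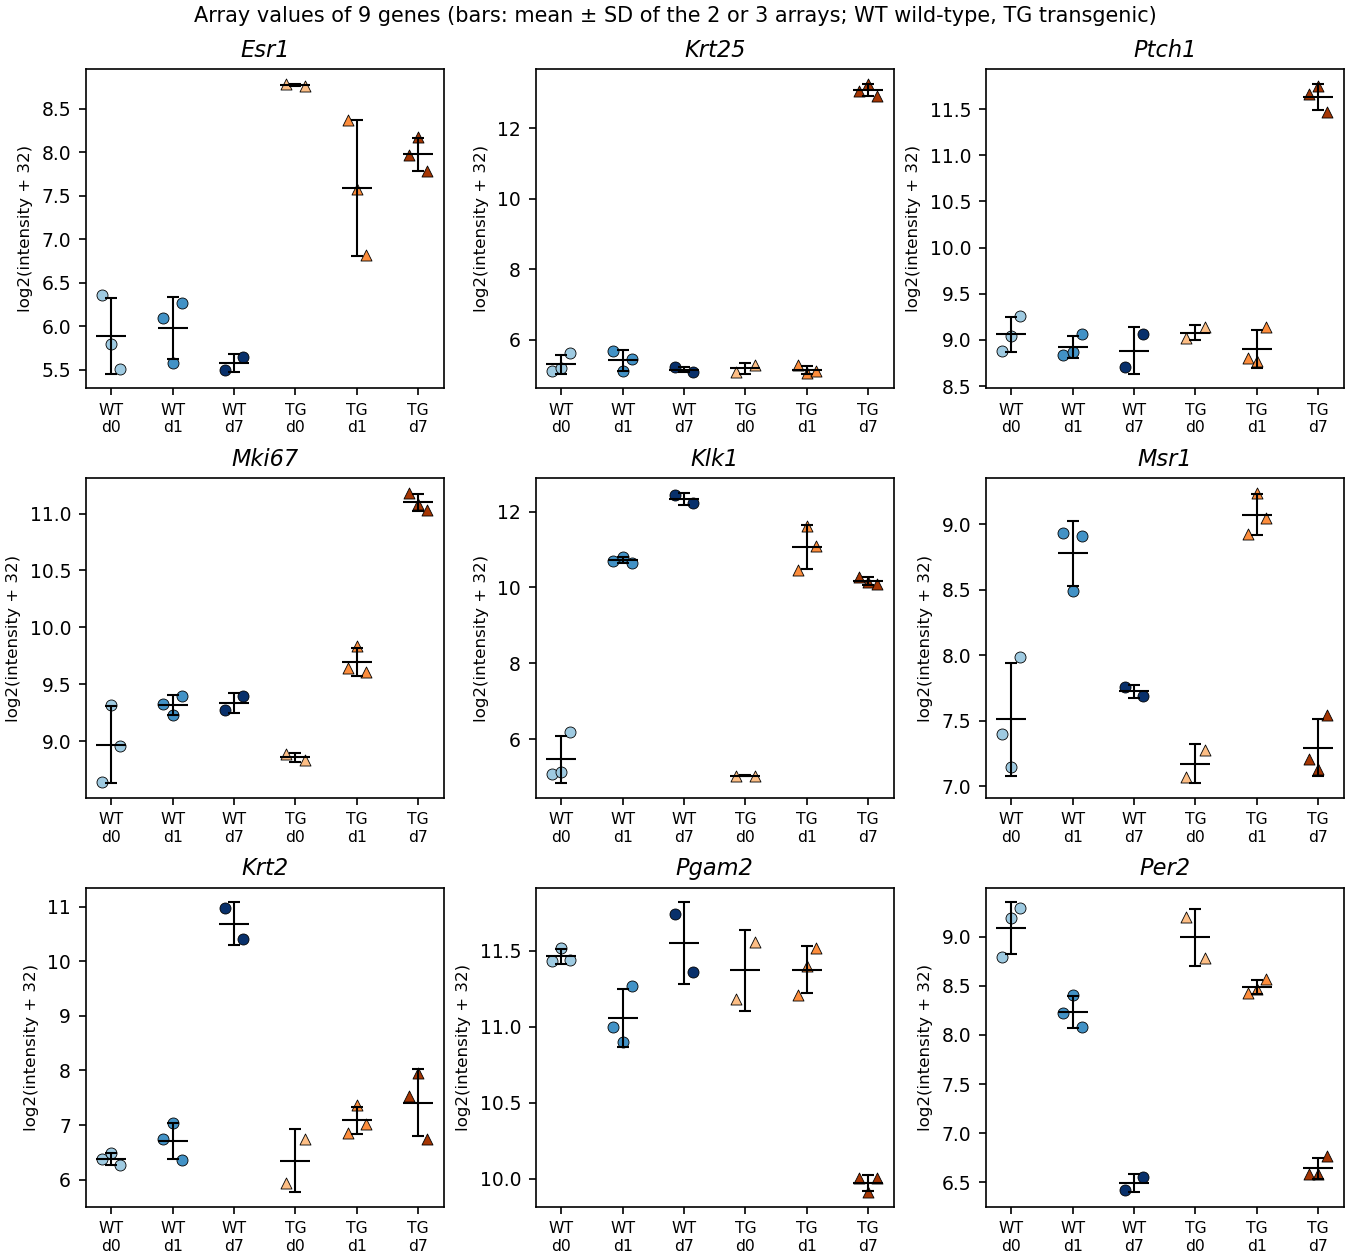
Intensity of 9 genes on each array, as log2(intensity + 32) on the y axis, by group on the x axis (WT wild-type, TG transgenic, d days of 4-hydroxytamoxifen); points are arrays and bars the mean ± SD of 2 or 3 arrays. Krt25 reaches 8655 ± 1026 in transgenic day 7 skin, and Klk1 is higher at days 1 and 7 than at day 0 in both genotypes.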

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

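The test of equal dilution below was chosen after the result was seen, and the test of array scaling before. The genotypes differed in their change to day 1 at 26 genes in the direct test of that difference. The change in transgenic skin minus that in wild-type skin was 1.81 for Tnfrsf12a, 1.65 for Cdr2l, 1.50 for Gm13889, -1.67 for 6820431F20Rik, -1.60 for Wdfy3 and -1.37 for Kdm7a. The other, dim probe set of Gm13889 went the other way, from 24.3 to 16.6 in transgenic and from 12 to 33.8 in wild-type skin. That of Tnfrsf12a changed less than the one used, from 225 to 262 in transgenic and from 163 to 144 in wild-type skin. In limma the count was 0 without transgenic day 0 replicate 2, transgenic day 1 replicate 1 or wild-type day 0 replicate 2, where 973, 1378 and 1113 genes had an unadjusted p under 0.05. It was 10 without transgenic day 0 replicate 1, 12 and 13 without transgenic day 1 replicates 2 and 3, 8 without transgenic day 7 replicate 1, 9 and 7 without wild-type day 0 replicates 1 and 3, and 3, 15 and 4 without wild-type day 1 replicates 1, 2 and 3. Each of these genes missed the threshold where the count was 0, and Gm13889 did so without any 1 array but transgenic day 7 replicate 3 (1.32 to 1.68, adjusted p from 0.053 to 0.138). Tnfrsf12a missed it without any 1 of the day 0 and day 1 arrays or transgenic day 7 replicate 1 (1.61 to 1.97, adjusted p from 0.0503 to 0.138). For 6820431F20Rik this held without any 1 day 1 array, transgenic day 0 replicate 2, transgenic day 7 replicate 1, or wild-type day 0 replicate 2 or 3 (-1.80 to -1.28, adjusted p from 0.0503 to 0.186). Cdr2l missed it also without transgenic day 0 replicate 1, wild-type day 0 replicate 3 or wild-type day 1 replicate 3 (1.66, 1.60 and 1.48, adjusted p = 0.0525, 0.0598 and 0.056), and Wdfy3 without wild-type day 1 replicate 1 (-1.48, adjusted p = 0.0511). Gm13889 also missed it without further scaling (adjusted p = 0.158), with a smaller added value (0.0604) and with only the groups compared (0.0661).

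The genotypes differed in their change to day 7 at 2154 genes in the same kind of test. Krt25 (8.04), Krt27 (6.15), Krt71 (5.95), Krt33a (5.92), Pmel (2.80), Ptch1 (2.73), Bambi (2.53), Gli1 (2.48), Mki67 (1.87), Ccnd1 (1.69) and Ctnnb1 (0.39) were on the higher side. Krt2 (-3.25), Klk1b27 (-2.93), Pon1 (-2.81), Sprr1b (-2.42), Pgam2 (-1.49), Tek (-1.47), Adgre1 (-1.28) and Aif1 (-1.11) were on the lower side. Ctnnb1 missed the threshold without further scaling (0.28, adjusted p = 0.666). It also missed it without transgenic day 0 replicate 2 (0.34) or wild-type day 7 replicate 2 (0.31). Its other probe sets, not used for the gene, went from 1090 to 2070 and from 2310 to 3820 in transgenic skin by day 7. In wild-type skin they went from 986 to 1020 and from 2130 to 2150. Among lists, the medians on the higher side were 4.33 for the inner root sheath, 2.59 for the hair shaft, 1.59 for melanocytes, 1.40 for Hedgehog genes, 1.35 for the cell cycle, 0.97 for placode and matrix regulators, 0.72 for BMP genes, 0.70 for Wnt and β-catenin targets and 0.19 for Wnt ligands, receptors and antagonists. On the lower side they were -1.08 for muscle, -1.06 for macrophages, -0.92 for adipocytes, -0.91 for Schwann cells and nerve, -0.74 for endothelium, -0.65 for interferon response, -0.58 for T cells, -0.57 for xenobiotic response, -0.37 for differentiated epidermis and -0.16 for dermal fibroblasts. Of these 19 lists the inner root sheath and Wnt target lists alone held with an estimated correlation, at an adjusted p of 0.024 each. The T cell call was lost without transgenic day 0 replicate 1 (-0.68, adjusted p = 0.0743), transgenic day 7 replicate 1 (-0.53, adjusted p = 0.0593) or wild-type day 0 replicate 1 (-0.64, adjusted p = 0.0529), in a range from 0.00946 to 0.284 over the alternatives with a preset correlation. The fibroblast call was lost without transgenic day 0 replicate 1 (-0.19), transgenic day 7 replicate 1 (-0.11) or 2 (-0.14), wild-type day 0 replicate 2 (-0.10) or wild-type day 7 replicate 1 (-0.15), at adjusted p-values from 0.0558 to 0.128, where the alternatives with a preset correlation ranged from 0.00308 to 0.128.

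Markers of muscle, fat, vessels and macrophages lay lower in transgenic than in wild-type skin by that difference, while follicle genes lay higher. For macrophages the lower value went with a rise in wild-type skin (median 1.07 at day 7). In transgenic skin no macrophage marker passed from day 0 to day 7. Growing follicles could dilute the RNA of all other cells alike. The dermal fibroblast list stood above the muscle list by 0.92 (95% bootstrap interval over members 0.43 to 1.13). These were the extremes of the cell type lists on the lower side, at -0.16 and -1.08. Between them lay macrophages (-1.06), adipocytes (-0.92), Schwann cells and nerve (-0.91), endothelium (-0.74) and T cells (-0.58). The pair was picked after these medians were seen, and the interval leaves out the spread between arrays. The test therefore cannot decide on equal dilution. Array scaling is not the cause of a fall of this size, since the mean change of 6 bright hybridisation controls was -0.09 ± 0.12 (SE over arrays), against -1.08 for muscle. A rise of fibroblast transcripts that offsets dilution, a different depth of tissue taken, and a change in these cells under the activated transgene stay open, and none of them was tested.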

How the results depend on the processing

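All alternatives here were planned, and the splits of arrays were chosen after the results were seen. Testing all probe sets singly and asking for a change of at least 2-fold were applied to gene counts only. Named genes and lists were not followed in those settings. In the remaining alternatives no reported list or named gene that was called passed the threshold in the other direction. The balance of higher and lower genes turned in some alternatives. Of 183 named gene values past the threshold, 175 stayed past it in all remaining alternatives with all arrays that measured the gene. With each array left out in turn, 173 stayed. Probe sets with a plain ending and the stricter filter left some named genes unmeasured. Of 58 list calls reported by name, 48 stayed in every such alternative, 53 with each array left out and 6 with an estimated correlation. Signal near background limits dim genes, as no detection calls were used. Where another cause is not named, the cause was not tested.

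Without further scaling the counts were 186 for transgenic day 1 against day 0, 1776 for transgenic day 7 against day 0, 1892 for day 7 against day 1, 465 for wild-type day 1 against day 0, 257 for wild-type day 7 against day 0, 7 and 724 for the differences in the changes to day 1 and day 7, 16 between genotypes at day 1 and 1744 at day 7. That setting moved the median of all genes by -0.124 in transgenic skin at day 1, -0.141 at day 7, -0.191 and -0.103 in the differences in the changes to day 1 and day 7, and 0.151 between genotypes at day 0. The share of higher genes went from 45.1% to 82.2% in wild-type skin at day 1, from 47.9% to 64.2% at day 7, from 50.9% to 38.8% in the difference at day 7 and from 48.1% to 50.1% between genotypes at day 7. At 2-fold or more it was 83.7% and 75.3% in wild-type skin at days 1 and 7. Over probe sets tested singly it was 53.7% and 56.2% for transgenic day 7 against day 0 and day 1, 53.1% and 53.2% in wild-type skin at days 1 and 7, and 43.1% and 52.6% between genotypes at days 1 and 7. With all probe sets tested singly, more tests were made and 5473, 6502, 3163 and 5567 passed for transgenic day 7 against day 0 and day 1, wild-type day 1 and the genotypes at day 7, and 45 for the difference at day 1. At 2-fold or more the counts were 150, 734 and 685 for transgenic day 1 against day 0 and day 7 against day 0 and day 1, 166 for wild-type day 1 and 166 for day 7, 16 and 717 for the differences, and 11 and 778 between genotypes at days 1 and 7. With only the groups compared, fewer arrays gave 453 for transgenic day 1, 12 for the difference at day 1 and 27 between genotypes at day 1. For the difference at day 1, no filter gave 8, no variance trend 15 and array weights 40. Plain probe sets gave 54 between genotypes at day 1.

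Leaving out each array gave 233 to 1063 for transgenic day 1 against day 0, with 594 and 233 without transgenic day 0 replicates 1 and 2, and 633 and 637 without transgenic day 1 replicates 1 and 2. Wild-type day 1 gave 1178 to 2179, with 1225 without wild-type day 0 replicate 2 and 1178 without wild-type day 1 replicate 1. Wild-type day 7 gave 328 to 1179, with 647 without wild-type day 0 replicate 2, and 328 and 447 without wild-type day 7 replicates 1 and 2. The difference at day 1 gave 0 to 24. Between genotypes at day 1 the counts were 17 to 1.3e+02, with 29 and 22 without transgenic day 1 replicates 1 and 3, 73 without transgenic day 7 replicate 1, 17, 19 and 75 without wild-type day 1 replicates 1, 2 and 3, and 63 without wild-type day 7 replicate 1. At day 0 limma gave 0 without transgenic day 0 replicate 1 or 2 (637 and 250 genes at an unadjusted p under 0.05) and 2 without wild-type day 1 replicate 1. For transgenic day 7 against day 0 and day 1, the difference at day 7 and the genotypes at day 7 the ranges were 2511 to 3605, 3167 to 4038, 1461 to 2360 and 2526 to 3773. Where 1 array of a group remained, it was assumed to vary like the other groups.

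With an estimated correlation, which widens the error of a list's mean, calls were lost at unchanged medians, and those reported by name are given here. Of all calls, 12 of 12 were lost in each change to day 1, 17 of 19 in transgenic skin from day 0 to day 7, 15 of 21 from day 1 to day 7, 6 of 7 in wild-type skin at day 7, 17 of 19 in the difference at day 7, 1 of 1 between genotypes at day 0 and 19 of 21 at day 7. For transgenic day 1 against day 0 those named were macrophages 1.13, cell cycle 0.62, fibroblasts 0.34 and differentiated epidermis -0.25. For wild-type day 1 they were macrophages 1.27, cell cycle 0.52, fibroblasts 0.24, basal -0.45 and differentiated epidermis -0.24, and cholesterol -0.41. For transgenic day 7 against day 0 they were hair shaft 3.13, melanocytes 1.73, cell cycle 1.68, Hedgehog 1.16, placode 0.90, Wnt targets 0.37, BMP 0.35, basal -0.23 and differentiated epidermis -0.44, immediate early genes -0.46, endothelium -0.58, interferon -0.59, xenobiotic response -0.68, T cells -0.79, Schwann cells -0.98, muscle -1.05 and fat -1.26. For day 7 against day 1 they were fibroblasts -0.18, muscle -0.83 and macrophages -1.09, for wild-type day 7 fibroblasts 0.39 and macrophages 1.07, and between genotypes fibroblasts -0.13 at day 0, and muscle -1.12 and macrophages -1.10 at day 7. For the difference at day 7 they were hair shaft 2.59, melanocytes 1.59, Hedgehog 1.40, cell cycle 1.35, placode 0.97, BMP 0.72, Wnt ligands 0.19, fibroblasts -0.16, differentiated epidermis -0.37, xenobiotic response -0.57, T cells -0.58, interferon -0.65, endothelium -0.74, Schwann cells -0.91, fat -0.92, macrophages -1.06 and muscle -1.08.

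Other settings lost reported list calls as follows. Plain probe sets gave, for transgenic day 7 against day 0, basal epidermis -0.05 and Schwann cells -0.63, and for the difference at day 7 Wnt ligands 0.15 and Schwann cells -0.66. The stricter filter, with fewer genes, gave immediate early genes -0.38, T cells -0.80 and endothelium -0.44, and for the difference fibroblasts -0.16 and T cells -0.63. No filter gave T cells -0.11 and, for the difference, -0.34, and gained calls for red blood cells (0.73) and for clock genes in the difference (-0.33). No further scaling gave immediate early genes -0.60, and 0.03 for fibroblasts between genotypes at day 0, where quantile normalization gave -0.09. That normalization gave fibroblasts -0.15 for the difference at day 7. With each array left out, medians lay from -0.46 to -0.35 for differentiated epidermis, -0.53 to -0.38 for immediate early genes and -1.88 to -0.08 for B cells at transgenic day 7, from -0.68 to -0.53 for T cells and -0.29 to -0.10 for fibroblasts in the difference, and from -0.16 to -0.05 for fibroblasts between genotypes at day 0. The call was lost for differentiated epidermis without transgenic day 7 replicate 3 (-0.38), for immediate early genes without transgenic day 0 replicate 1 (-0.42) or transgenic day 7 replicate 3 (-0.44), and for fibroblasts at day 0 without transgenic day 0 replicate 2 (-0.11) or wild-type day 0 replicate 3 (-0.05), and gained for B cells without transgenic day 0 replicate 2 (-1.88). In number of lists, the genotypes at day 1 gave 8 without further scaling, 5 without the filter, 2 with only the groups compared or array weights and 1 with no variance trend or a larger added value, against 0. The difference at day 1 gave 1 with only the groups compared and 2 with array weights, against 0. The genotypes at day 0 gave 2 with only the groups compared, against 1, and 5, 2 and 2 without transgenic day 0 replicate 1, transgenic day 0 replicate 2 or wild-type day 0 replicate 1. Xist, of transgenic day 7 against day 0, gained a call on plain probe sets (1.12, adjusted p = 0.00455), where another probe set stands for it.

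Replicate numbers are shared between groups, but 7 of 36 pairs of same-numbered arrays correlated above 0.1 in their deviations (mean r = 0.005), and 6 of 16 arrays correlated best with their own number. With the replicate number as a block the difference at day 1 gave 4 genes, all lower, and of the 6 named there Tnfrsf12a (adjusted p = 0.0743), Cdr2l (0.052), 6820431F20Rik (0.0743), Wdfy3 (0.052) and Gm13889 (0.0885) were not called while Kdm7a was (0.0213). In that fit fibroblasts between genotypes at day 0 lost their call (-0.08), and the other counts stayed within 1.5 times, such as 3367 for transgenic day 7 against day 0. The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. In 1 of 10 splits, the real one, as many genes passed: 4009 for transgenic day 7 against day 1 (highest other 1), 2023 for wild-type day 1 against day 0 (highest other 0) and 118 between genotypes at day 1 (highest other 0). Every other split put part of the difference between the real groups into the spread of the test. Low counts there were thus largely fixed in advance and add no support.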

Other observations

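Dim regulators of follicle growth rose in transgenic skin at day 7 although they lay below the filter on dim probe sets. Lef1, a transcription factor that binds β-catenin, went from an intensity of 28.8 ± 3.03 (SD, n = 2) to 117 ± 12.4 (SD, n = 3), and was 33.5 ± 7.60 in wild-type skin at day 7. In a fit without the filter its log2 change was 1.29 ± 0.17 (SE, adjusted p = 4.11e-05), and the difference between genotypes in the change to day 7 was 1.10 ± 0.24 (adjusted p = 0.00585). Shh, the Hedgehog ligand of the growing follicle, went from 19.3 ± 24.1 to 93.1 ± 3.35, by 1.37 ± 0.23 (adjusted p = 0.000381). Edar, a receptor of the follicle placode that was chosen after its values were seen, went from 9.98 ± 0.919 to 114 ± 4.52, by 1.79 ± 0.18 (adjusted p = 3.99e-06). The values of these genes are low, so their folds depend on the added intensity.

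Of the tests on the patterns that follow, those on clock genes and macrophage markers were chosen after the results were seen, and that on glucocorticoid-responsive genes before. Clock genes fell at day 7 in both genotypes, 8 of 13 of them in wild-type skin, which argues against the transgene as the cause. Arntl, Clock, Cry1 and Nfil3 were taken for the test as genes of the phase opposite to Dbp and Per2. Their mean was higher by 0.29 ± 0.11 (SE over arrays) in wild-type skin and by 0.33 ± 0.11 in transgenic skin. The mean does not show that each of them rose. A rise of this mean could come from skin taken at another phase of the day at day 7 than at day 0. Per2 went from 518 over 271 at day 1 to 58.1 in wild-type skin and from 483 over 327 to 68.2 in transgenic skin, and Hlf from 783 over 532 to 313 in wild-type skin. As the labels give no hour of sampling, a graded effect of drug or time on the clock stays open.

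Macrophage markers rose at day 1 in both genotypes, 17 of 18 of them in wild-type skin, which argues against the transgene as the cause. A lower share of the main cell types would raise the markers of all other cells alike. The macrophage median exceeded that of the endothelial list by 1.06 in wild-type skin (95% bootstrap interval over members 0.61 to 1.36). That interval leaves out the spread between arrays. Drug, handling and time cannot be told apart, since 0 of 16 arrays came from skin given vehicle. Entry of macrophages into the skin or a change in resident cells may underlie the rise, and neither was tested.

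Because Tsc22d3, a gene induced by glucocorticoids, stood higher in transgenic than in wild-type skin at day 1, a list of 16 other glucocorticoid-responsive genes was tested. The mean difference of the 15 measured was 0.30 ± 0.08 (SE over arrays), with 13 above 0. In limma 0 of the 15 passed over all genes, in a comparison with 1818 genes at an unadjusted p under 0.05, the largest differences being those of Pdk4 (0.80, adjusted p = 0.2) and Errfi1 (0.73, adjusted p = 0.0704). A candidate explanation is a stronger stress hormone response in the transgenic day 1 mice. Tsc22d3 went from 2710 to 3600 in transgenic and from 2660 to 1670 in wild-type skin, so a weaker response in the wild-type day 1 mice stays as open, and strain, handling or hour could give either.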
